A study of Rattus norvegicus with 22 samples.

How the data were processed

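Liver RNA was sequenced from 22 Wistar rats at postnatal day 110, the offspring of mothers given a control diet or an obesogenic diet (maternal obesity, MO). The labels put 6 control males, 5 MO males, 6 control females and 5 MO females into 4 groups. Per the labels' protocols, RNA was extracted from 10 to 20 mg of tissue and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The submitters' processing notes name STAR 2.3.1j, Partek and the genome build rn5, without saying what each was used for. The annotation version, the counting rule and the treatment of reads that fit several transcripts are not given in the sources used here. The design text counts animals per group, and the labels do not give litters, so p-values measure the spread between these animals.

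Each sex had its own table, whose rows carry RefSeq transcript accessions. The 1365 male rows stand for 1347 transcripts, since 18 rows list a transcript again under a versioned accession, and the 69 female rows for 69. Male counts are of rows; with 1 row per gene there were 1327 genes, 46 higher and 1281 lower. The values per animal deposited by the authors are in RPM, reads scaled to a common library total, with 1 added. This was inferred from the values because the file headers name no unit. The lowest value was exactly 1. After 1 was subtracted, 81.4% to 86.6% of the low values (under 9 RPM) in the male libraries were whole multiples of 1 step per library within 0.02 of a read, and 54.5% to 61.1% in the female libraries. The remaining fractional values kept the step from giving whole reads, so no test on counts was run. The steps put the depth at 7890000 to 11170000 reads in control males, 10530000 to 11590000 in MO males, 9180000 to 11770000 in control females and 10470000 to 11710000 in MO females, so that 1 read was worth 0.085 to 0.127 RPM.

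The fold column deposited by the authors is a log2 value, the size of the difference of mean log2 values between MO and control animals, with the sign in a separate column. It was recovered from the values for 1365 of 1365 male rows and 67 of 69 female rows. The p-values deposited by the authors were recovered for the same rows as unadjusted p-values of an equal-variance model on log2 values. Of the 2 unmatched female rows, Sgk1 had a p-value of 0.16519 in the authors' deposited table against 0.0494 from its values, and the other is not reported here. No male row had a deposited p of 0.05 or more, and no row of either table had a change under 0.48 on the log2 scale, about 1.4-fold. Both tables therefore hold rows that had already been selected for a difference, and the transcripts outside them are not analysed here.

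The design fixed before the data were examined named a count model for counts and limma for normalised values, and the values here called for the latter. Each sex was fitted separately with limma 3.58.1 (limma-trend, R 4.3.3) on log2(RPM + 1), so a pseudocount of 1, without a filter on low values, and p-values were adjusted with the Benjamini-Hochberg procedure over the rows of that table at a threshold of 0.05. Fold changes are on this log2(RPM + 1) scale, which understates the change of low genes. Because rows had been listed for an unadjusted p under 0.05, nearly all of them pass such an adjustment by construction, and the adjusted p is no false discovery rate over the expressed transcripts. The limma spread was estimated from selected rows as well, which makes its p-values too small. On simulated libraries with the male depths and spread, 1365 genes and 200 of them changed, the fit recovered 89% of the changes of 1 and 100% of those of 2 on the log2 scale, with 5 false calls among 194. With the female values, 69 genes and 20 of them changed, it recovered 50% and 100%, with 0 false calls among 15. The simulated rows were not selected, had as many rises as falls and held no shift shared by a library. These rates therefore do not carry over to the selected rows listed here.

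The effect of the diet was compared between the sexes with limma over the 4 groups for the symbols present in both tables. The 41 gene lists (metabolic pathways, complexes, signalling, zonation and markers of other cell types) were fixed before the data were examined. Without a table of all measured transcripts no enrichment can be tested, so the listed members were counted, and the split into higher and lower members was compared with the other listed genes by a two-sided Fisher's exact test for lists with at least 5 listed members. For these counts 1 row per gene was kept, that with the smallest p, which left 1327 male and 68 female genes. The reference table (assembly GRCr8) was used for current names only, and matched 1346 of 1365 male and 66 of 69 female rows. Chromosomes are those of the deposited tables.

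Named genes followed a rule fixed before the data were examined. Per sex these were the 8 passing genes with the largest positive and the 8 with the largest negative log2 fold change, leaving out symbols that begin with LOC, RGD or MGC and genes whose higher group mean was under 1 RPM. Added were up to 4 members with the smallest p of each list with at least 3 listed members, genes listed in both sexes, and any member of a list with a count of 5 or fewer. LOC102723236, LOC257642, LOC100134871 and Irs2 lie outside the rule and were chosen after their values were seen. Alternatives were median-centred libraries, a filter at a mean of 1 RPM, an exact permutation test, pseudocounts of 0.1 and 10, a replicate block, adjusted p under 0.01 and 0.10, limma without trend and with array quality weights, and each library left out in turn. Rows share reads with transcript variants and near-identical paralogs, so members of the Ugt2, Cyp2, Cyp4a, Sult1c, Gstm, Mt, olfactory receptor and RT1 families are uncertain. Overlapping and antisense genes cannot be told apart where the counting did not use strand, which is not stated. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.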

Results

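The liver transcriptome was measured by RNA sequencing in young adult Wistar rats whose mothers had received a control diet or an obesogenic diet. Each animal gave 1 library. The comparison of offspring of obese mothers (MO) with controls was made within each sex, in 6 control and 5 MO males and in 6 control and 5 MO females, all at postnatal day 110. Depth as read from the values was 9360000 ± 1140000 reads (SD, n = 6) in control males, 11030000 ± 460000 reads (SD, n = 5) in MO males, 10790000 ± 1070000 reads (SD, n = 6) in control females and 11110000 ± 470000 reads (SD, n = 5) in MO females. The deposited tables hold transcripts already selected for a difference, in 1365 rows for males and 69 for females. Of the male rows 18 list a transcript a second time, and counts are of rows.

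The first comparison asked which liver transcripts differed between male offspring of obese and control mothers. Of the listed male rows 1317 were lower and 48 were higher in MO animals. Among the lower ones were Npas2, a transcription factor of the clock, the thyroid hormone receptor Thra and the thymidine phosphorylase Tymp. Among the higher ones were Rgs16, a regulator of G protein signalling, Pdk4, the kinase that inhibits pyruvate dehydrogenase, and Nampt, the rate-limiting enzyme of NAD salvage. Most lower rows differed little. Their median log2 fold change was -0.58, and 71 of them reached a change of 1 or more on the log2 scale, as did 14 of the higher ones.

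Rgs16 on chromosome 13 had the largest increase, from 1.72 ± 1.24 RPM (SD, n = 6) in control males to 28.97 ± 19.38 RPM (SD, n = 5) in MO males. Its log2 fold change was 3.30 ± 0.39 (SE; limma adjusted p = 8.4e-06), and 5 of 5 MO animals lay above every control. Nampt rose from 56.8 ± 11.5 RPM (SD, n = 6) to 159.8 ± 44.3 RPM (SD, n = 5) and Pdk4 from 14.9 ± 3.30 RPM (SD, n = 6) to 50.6 ± 18.4 RPM (SD, n = 5), again with 5 of 5 MO animals above every control. Socs2, a feedback inhibitor of growth hormone signalling, rose by 2.23 ± 0.44 on the log2 scale (SE; limma adjusted p = 0.0012). The other genes with the largest increases were Nat8 (1.79 ± 0.39, SE), the mitochondrial carrier Slc25a30 (1.59 ± 0.43, SE), the cell cycle kinase Wee1 (1.34 ± 0.25, SE) and the transglutaminase Tgm1 (1.33 ± 0.30, SE). Each of these 8 genes was higher than the control mean in 5 of 5 MO animals. Wee1 was above every control in 5 of 5 MO animals, Socs2, Nat8 and Tgm1 in 4 of 5 and Slc25a30 in 1 of 5. The controls were not alike for Wee1 and Nat8. Control males 1, 3 and 5 were at 1.5 to 2.06 RPM of Wee1 and 2.53 to 4.12 RPM of Nat8. Control males 2, 4 and 6 were at 4.94 to 6.78 RPM and 12.1 to 24.4 RPM. All 8 remained higher after the libraries were centred on their medians. This was fixed in advance, since centring subtracts a shift of -0.58 and so raises every change.

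**Figure D1:**
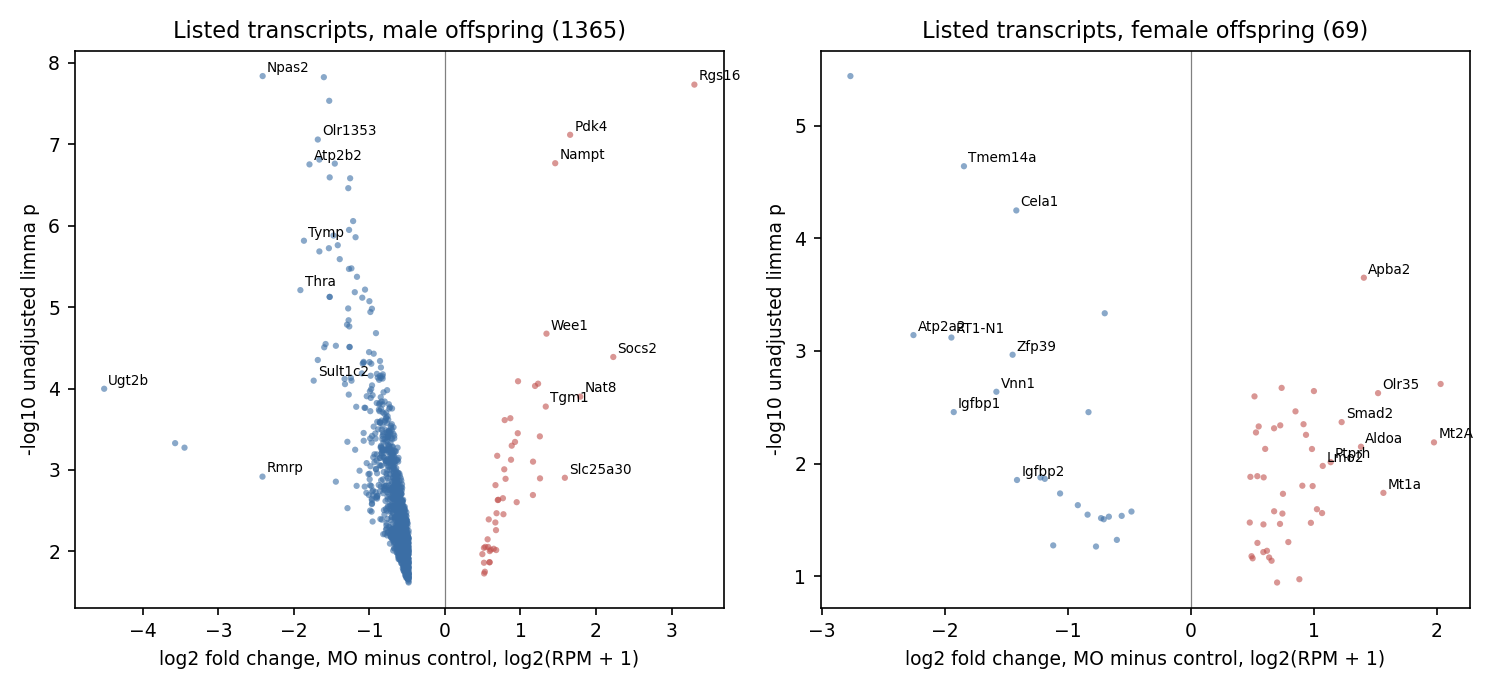
Log2 fold change (MO minus control, on the log2(RPM + 1) scale) against -log10 of the unadjusted limma p for the 1365 listed male rows (left) and the 69 listed female rows (right), 1 point per row, red for higher and blue for lower in MO offspring. Male points lie mostly on the lower side (1317 of 1365), female points on both sides (45 higher, 24 lower), and the gap around 0 is where no transcript was listed.

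Among the transcripts with the largest decreases, the clock transcription factor Npas2 on chromosome 9 went from 7.48 ± 3.51 RPM (SD, n = 6) to 0.484 ± 0.395 RPM (SD, n = 5). Its log2 fold change was -2.41 ± 0.28 (SE; limma adjusted p = 8.4e-06), with 5 of 5 MO animals below every control. Thra, the thyroid hormone receptor alpha, went from 19.5 ± 10.6 RPM (SD, n = 6) to 3.62 ± 0.361 RPM (SD, n = 5), and the thymidine phosphorylase Tymp from 505.3 ± 203.5 RPM (SD, n = 6) to 134.8 ± 46.03 RPM (SD, n = 5). Control males 2 and 4 had 5.6 and 6.59 RPM of Thra, and the other controls 24.2 to 28.9 RPM. The calcium pump Atp2b2 (-1.79 ± 0.24, SE) and the olfactory receptor Olr1353 (-1.68 ± 0.22, SE) were lower than every control in 5 of 5 MO animals, and the sulfotransferase Sult1c2 (-1.74 ± 0.36, SE) in 3 of 5. Ugt2b, a glucuronosyltransferase on chromosome 14, had the largest decrease (-4.51 ± 0.96, SE; limma adjusted p = 0.0018), but the MO animals were not alike. MO males 1, 2 and 3 were at 16, 12.5 and 14.5 RPM, and MO males 4 and 5 were at 1820 and 1175 RPM, within the control range of 1060 to 3373 RPM.

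**Figure D2:**
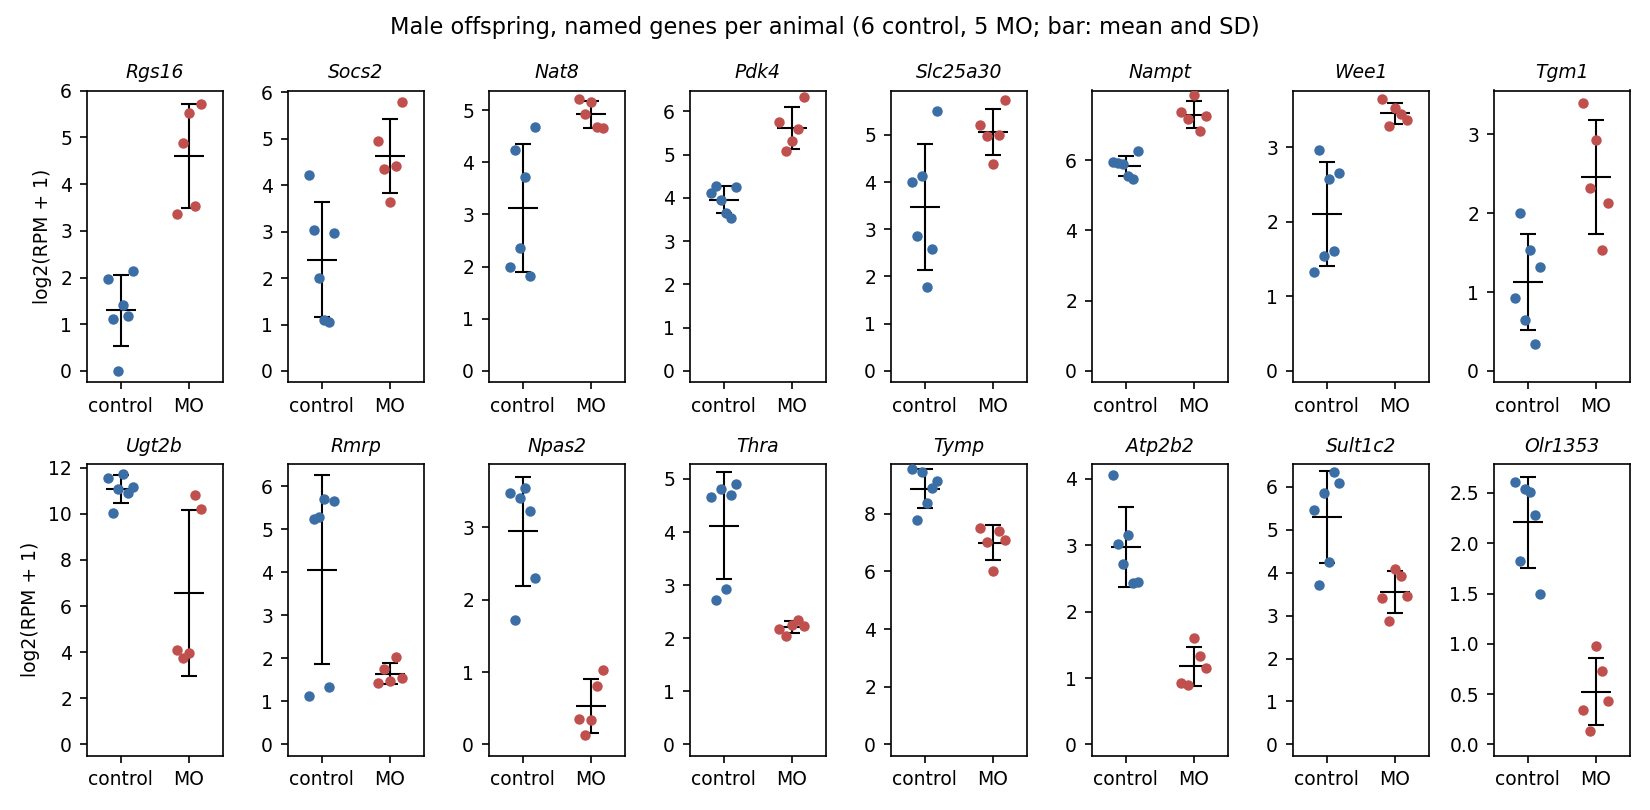
Log2(RPM + 1) per animal of the 8 male genes with the largest increase (upper row) and the 8 with the largest decrease (lower row) under the naming rule, 6 control (blue) and 5 MO (red) animals, with mean and SD as black bars. Ugt2b has MO animals at 2 separate levels, and Rmrp has control animals at 2 separate levels. In Thra, Sult1c2, Wee1 and Nat8 the control animals also fall into a lower and a higher set.

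Rmrp, the RNA part of a ribonuclease complex, was listed as lower (-2.42 ± 0.65, SE), and so was LOC102723236, the RNA of the signal recognition particle. Both RNAs carry no poly(A) tail. Rmrp was at 36.9 to 51.2 RPM in control males 2, 3, 4 and 6, at 1.20 and 1.52 RPM in control males 1 and 5, and at 1.71 to 3.11 RPM in the 5 MO males. LOC102723236 was at 401 to 642 RPM, at 15.9 and 6.13 RPM, and at 6.71 to 27.6 RPM in the same animals. When the MO males were compared with control males 1 and 5 alone, an alternative added after these values had been seen, Rmrp had a log2 fold change of 0.41, and 531 of the 1365 rows passed the limma threshold, 38 higher and 493 lower. The direction was kept by 1314 of 1317 lower and 48 of 48 higher rows, which had been selected in part on these 2 controls, and the median log2 fold change of the lower rows was -0.54 in place of -0.58.

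**Figure D3:**
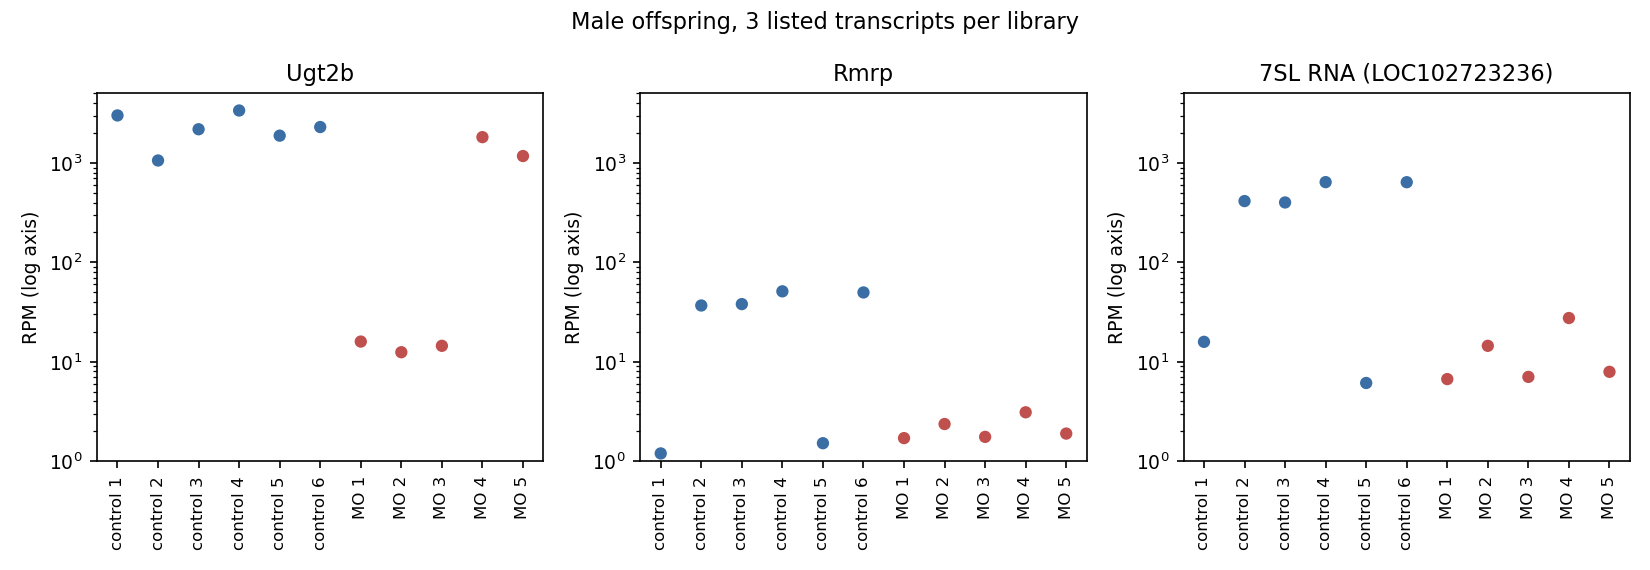
RPM on a log axis of Ugt2b, Rmrp and the signal recognition particle RNA (LOC102723236) in each of the 11 male libraries, controls in blue and MO in red. Ugt2b is at 12.5 to 16 RPM in MO males 1 to 3 alone, and both other RNAs are high in control males 2, 3, 4 and 6.

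Of the 41 fixed gene lists, 37 had a member in the male table, and in 30 of these every listed member was lower. The longest was amino acid and urea metabolism, with 28 listed members of 66, all lower. Cth, which makes cysteine from cystathionine, went from 987 ± 179 RPM (SD, n = 6) to 324.9 ± 59.3 RPM (SD, n = 5). This was a log2 fold change of -1.60 ± 0.19 (SE; limma adjusted p = 8.4e-06), with 5 of 5 MO animals below every control. Bhmt, the betaine-homocysteine methyltransferase, went from 3900 ± 1465 RPM (SD, n = 6) to 1308 ± 374 RPM (SD, n = 5). Gldc of the glycine cleavage system (-1.39 ± 0.22, SE) and Kynu of tryptophan breakdown (-1.44 ± 0.28, SE) followed. The split of the list was that of the table as a whole (Fisher's exact p = 0.62), in which 1281 of 1327 genes were lower. In such a table a list of this length with every member lower cannot reach a small p.

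For the lists in this paragraph with 5 or more listed members, Fisher's exact p of the split was 1.0. With nearly all genes of the table lower, this was fixed for lists of their length whose members were all lower. Bile acid synthesis and transport had 5 listed members, all lower, led by Cyp8b1, the sterol 12-alpha-hydroxylase that sets the cholic acid share (1017 ± 433 to 332.3 ± 192.3 RPM; SD, n = 6 and 5), and the uptake transporter Slco1b2 (-0.99 ± 0.24, SE). Glucose metabolism had 7, all lower, among them Ppp1r3c, which targets phosphatase to glycogen (-1.53 ± 0.26, SE), Gckr (-1.06 ± 0.18, SE) and the liver glycogen phosphorylase Pygl (-1.0 ± 0.20, SE). Fatty acid and triglyceride synthesis had 5, all lower, with Dgat2, of triglyceride synthesis, at -0.74 ± 0.21 (SE) and the elongase Elovl5 at -0.99 ± 0.30 (SE). Xenobiotic metabolism had 13, all lower, such as Ugt2a3 (-1.27 ± 0.27, SE) and the dioxin receptor Ahr (-1.19 ± 0.30, SE). The 6 listed male-predominant genes were lower too, and included the male-specific Cyp2c13 (2665 ± 666 to 1666 ± 194 RPM; SD, n = 6 and 5) and Cyp2a2 (-0.87 ± 0.18, SE). The female-predominant Cyp2a1 was lower as well (-0.82 ± 0.20, SE). The other listed member of the fixed female-predominant list, Hsd3b5 (-0.58 ± 0.18, SE; 0.00 after centring), is known as a male-specific gene of rat liver and was misplaced there. Stat5a and Stat5b, which relay growth hormone signals, were both at -0.61.

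Of the lists tested, 3 had listed members that went both ways. In fatty acid oxidation and ketogenesis Pdk4 and Ehhadh, a peroxisomal beta-oxidation enzyme (0.87 ± 0.22, SE), were higher and 4 members were lower, with Acox2, a peroxisomal oxidase of bile acid side chains, at -1.27 ± 0.21 (SE). In lipoprotein and lipid handling Angptl4, an inhibitor of lipoprotein lipase, went from 145.8 ± 42.9 RPM (SD, n = 6) to 279.3 ± 47.3 RPM (SD, n = 5) and the lipid droplet protein Plin2 from 254.2 ± 51.7 RPM (SD, n = 6) to 460.5 ± 174.4 RPM (SD, n = 5), with 3 members lower. In insulin signalling Socs2 and Irs2, the insulin receptor substrate (0.65 ± 0.23, SE), were higher and 6 members lower. The Fisher's exact p-values of these splits were 0.016, 0.011 and 0.029, and after Benjamini-Hochberg adjustment over the 20 lists tested they were 0.16, 0.16 and 0.19, so 0 lists passed.

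Oxidative phosphorylation had 7 listed members of 93, with Ndufb10 of complex I at -0.56 ± 0.18 (SE), and mitochondrial ribosomal proteins had 14 of 95, with Mrps27 at -0.57 ± 0.16 (SE). All were lower on the deposited scale, but after centring 7 of 7 and 12 of 14 lay above the median change of the listed transcripts. The 28 amino acid genes were divided into 19 below and 9 above that median change. The 5 bile acid genes, the 6 male-predominant genes and the 5 pericentral hepatocyte genes were all below it. Oat (-1.06 ± 0.24, SE) and the Wnt target Axin2 (-0.79 ± 0.22, SE) were among the pericentral genes. Below it were also 5 of 7 glucose, 4 of 5 fatty acid synthesis, 10 of 13 xenobiotic, 5 of 7 antioxidant and 3 of 7 complement and acute phase genes. Of the 5 listed periportal genes 3 were below it and 2 above, with the histidine ammonia-lyase Hal at -1.08 ± 0.21 (SE). These positions were not tested as groups, and members above the median change lie close to it because no change under 0.48 was listed. After centring, 2 of the 28 amino acid genes and 0 genes of the other lists in this paragraph passed the limma threshold, and Cyp2c13 was at -0.06.

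Of the 7 listed complement and acute phase genes, all lower, Mbl2 of the lectin pathway was at -0.75 ± 0.18 (SE) and C1s at -0.62 ± 0.18 (SE). The 7 antioxidant genes, again all lower, included Gstm7 (-0.72 ± 0.17, SE) and catalase, Cat, which went from 3230 ± 469 RPM (SD, n = 6) to 2063 ± 331 RPM (SD, n = 5). Markers of other cell types gave 13 listed genes of 213, all lower, such as Pdgfrb of stellate cells (-0.70 ± 0.16, SE) and Krt19 of bile duct cells (-0.60 ± 0.18, SE), and no member of the Kupffer cell, neutrophil or erythroid lists was in the table. Every count per list was the same when adjusted over the list alone.

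**Figure D4:**
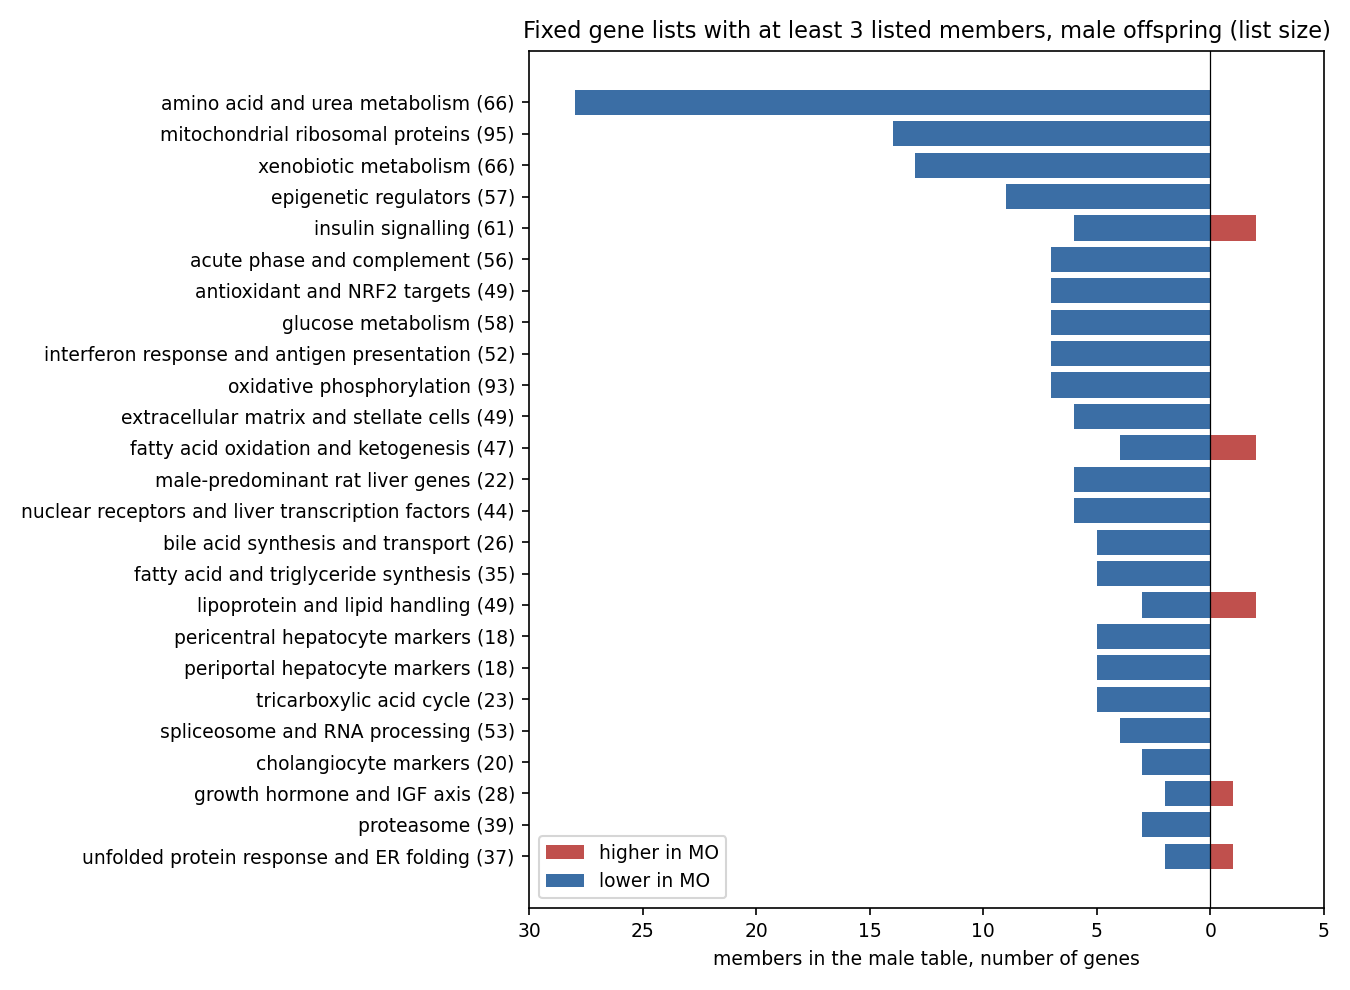
Number of listed male genes per fixed gene list with at least 3 listed members, higher in MO offspring to the right and lower to the left, with the list size in brackets. Amino acid and urea metabolism has 28 lower members, and higher members appear in 5 of the lists drawn.

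All 1365 male rows passed the limma threshold over the table, which follows from their selection. By the unadjusted p-values of the authors' equal-variance model, recomputed from the values, at least 1 call at 5% would exist if no more than 15627 transcripts had been tested and all others had a larger p. Centring each library on its median left 72 rows past the threshold, 48 higher and 24 lower, against 48 and 1317 on the deposited scale. Npas2, Thra, Tymp, Atp2b2, Olr1353, Cth, Gldc and Acox2 were among these 24, and the other lower genes named here were not. The listed transcripts took 12.02% ± 1.91 of all reads in control males (SD, n = 6) and 7.55% ± 0.906 in MO males (SD, n = 5).

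The second comparison asked the same of female offspring. Of the 69 listed female transcripts 45 were higher and 24 lower in MO animals. The metallothioneins Mt2A and Mt1a, which bind zinc and copper, and 4 genes of glucose metabolism were higher, while Igfbp1 and Igfbp2, which bind insulin-like growth factors, were lower. The limma fit passed 56 transcripts over the table, 35 higher and 21 lower, and these were mostly of low abundance, with a median of 2.93 RPM over the table.

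Mt2A went from 216.5 ± 189.7 RPM (SD, n = 6) in control females to 680 ± 484 RPM (SD, n = 5) in MO females. Its log2 fold change was 1.98 ± 0.67 (SE; limma adjusted p = 0.018), with 5 of 5 MO animals above the control mean and 3 of 5 above every control. Mt1a was at 1.57 ± 0.63 (SE; limma adjusted p = 0.031). Apba2, a neuronal adaptor protein, went from 1.42 ± 0.355 RPM (SD, n = 6) to 5.93 ± 3.08 RPM (SD, n = 5), with 5 of 5 MO animals above every control (exact permutation p = 0.0022, the smallest that 6 against 5 animals can give). Other large increases were those of the olfactory receptor Olr35 (1.52 ± 0.46, SE), the glycolytic enzyme Aldoa (1.39 ± 0.48, SE) and Smad2, which relays signals of the TGF-beta family (1.23 ± 0.40, SE). The phosphatase Ptprh (1.14 ± 0.41, SE) and 1 transcript of Lmo2 (1.07 ± 0.39, SE) followed. A second transcript of Lmo2 went the other way (-0.48 ± 0.21, SE). LOC100134871, left out by the naming rule, was at 2.03 ± 0.60 (SE; limma adjusted p = 0.012).

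Igfbp1 went from 329 ± 182 RPM (SD, n = 6) to 96.3 ± 77.9 RPM (SD, n = 5). Its log2 fold change was -1.93 ± 0.60 (SE; limma adjusted p = 0.014), and it was below every control in 4 of 5 MO animals. Igfbp2 was at -1.41 ± 0.54 (SE; limma adjusted p = 0.027). Vnn1, a pantetheinase, went from 25.7 ± 11.04 RPM (SD, n = 6) to 8.28 ± 3.99 RPM (SD, n = 5) and Cela1, an elastase known from the pancreas, from 2.92 ± 2.14 RPM (SD, n = 6) to 0.354 ± 0.374 RPM (SD, n = 5), each with 5 of 5 MO animals below every control. Atp2a2, the calcium pump of the endoplasmic reticulum (-2.25 ± 0.59, SE), Tmem14a (-1.84 ± 0.36, SE), Zfp39 (-1.45 ± 0.40, SE) and the class I histocompatibility gene RT1-N1 (-1.94 ± 0.52, SE) were other large decreases. LOC257642, left out by the naming rule, had the largest change of the female rows (-2.77 ± 0.48, SE; limma adjusted p = 0.00025).

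**Figure D5:**
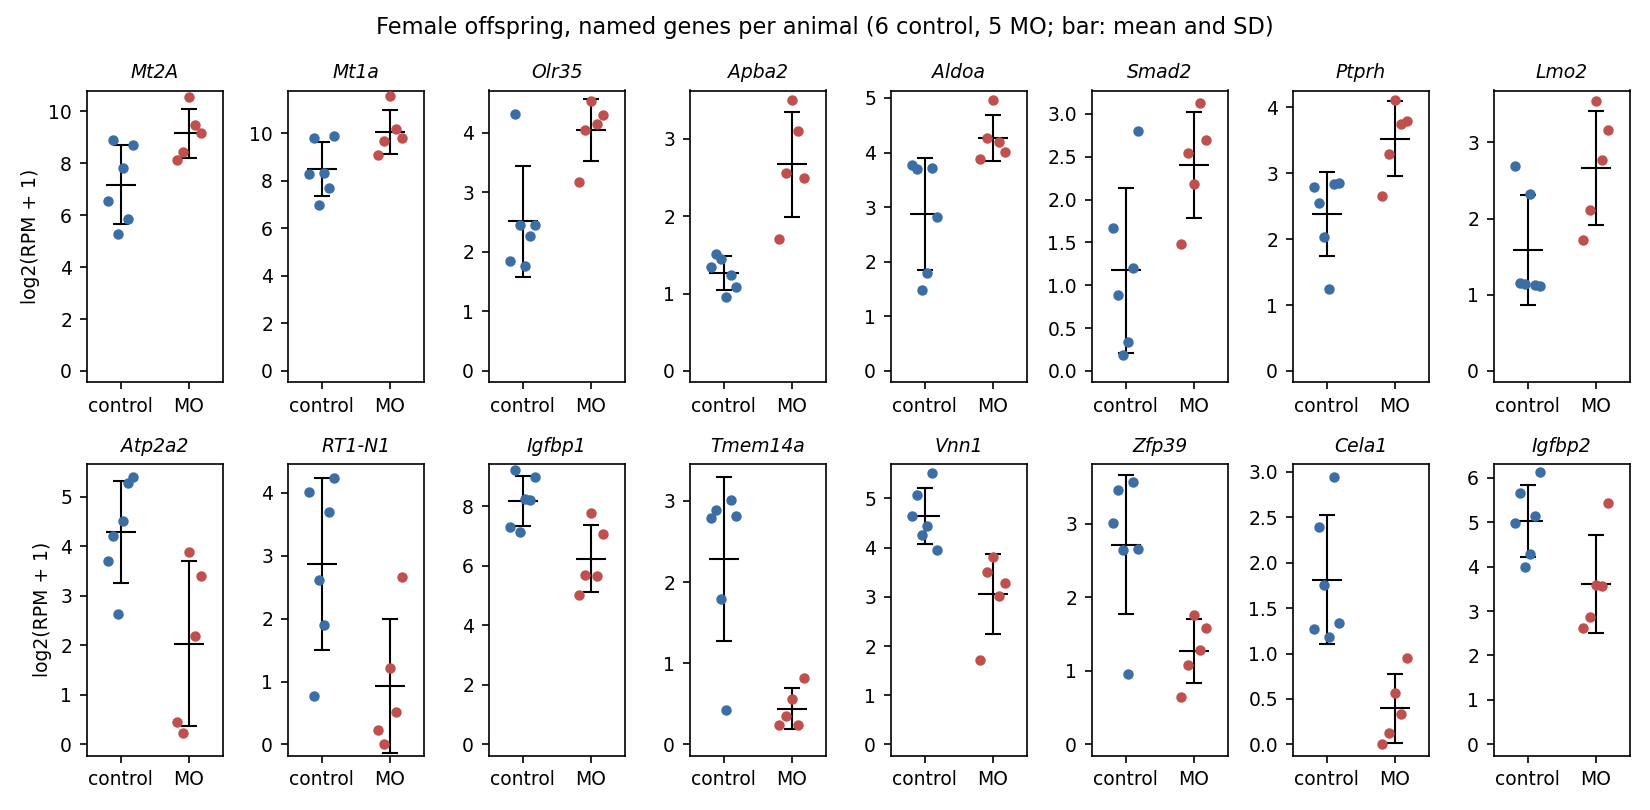
Log2(RPM + 1) per animal of the 8 female genes with the largest increase (upper row) and the 8 with the largest decrease (lower row) under the naming rule, 6 control (blue) and 5 MO (red) animals, with mean and SD as black bars. In Apba2, Aldoa, Vnn1 and Cela1 the 5 MO animals lie outside the control range, and in the other panels the groups overlap.

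Of the 41 gene lists 11 had a listed member in females and 0 had the 5 members needed for a test. All 4 listed glucose metabolism genes were higher. Among them were the glycolytic enzymes Aldoa (7.85 ± 5.03 to 19.0 ± 6.55 RPM; SD, n = 6 and 5) and Eno1 (0.99 ± 0.34, SE) and the glucagon receptor Gcgr (1.07 ± 0.46, SE). The glucocorticoid and fasting list held Igfbp1, Mt1a, Mt2A and the kinase Sgk1. Sgk1 did not pass (0.79 ± 0.39, SE; limma adjusted p = 0.059), so 3 of the 4 passed over the table and 4 adjusted over the list alone. Among genes that are higher in male than in female rat liver, Obp3 was lower (-0.70 ± 0.18, SE) and Cyp4a2, a fatty acid omega-hydroxylase, did not pass (-1.12 ± 0.55, SE; limma adjusted p = 0.061). Gadd45b (-1.22 ± 0.46, SE) was lower, and Mx1 (0.61 ± 0.21, SE) and Pparg (0.55 ± 0.18, SE) were higher at under 1 RPM. Mx1, Pparg and the higher transcript of Lmo2 no longer passed after centring. Of the 213 markers of other cell types in the fixed lists only Cela1 was listed. Transcripts outside those lists were not assigned to cell types.

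An exact permutation test in place of limma passed 4 of the 69 transcripts after adjustment, with 62 at an unadjusted p under 0.05. Of the female genes named here, Apba2, Vnn1 and Cela1 passed it. Mt2A, Mt1a, Igfbp1, Igfbp2, Aldoa, Eno1 and Gcgr were among those that did not (exact permutation adjusted p = 0.055 each). By the unadjusted p-values of the authors' equal-variance model, recomputed from the values, a call at 5% would exist only if no more than 111 transcripts had been tested, all others having a larger p. Centring on the library medians gave 21 higher and 24 lower calls in place of 35 and 21, and leaving out MO female 2 or MO female 5 left 34 or 37 calls. With the replicate number as a block 26 transcripts passed. The limma calls of Mt1a, Gcgr, Pola2, Igfbp2, Gadd45b, Mx1 and Lmo2 ended when 1 library was left out, for 7, 6, 6, 3, 3, 2 and 2 of the 11 libraries.

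The third comparison asked whether the effect of maternal diet differed between the sexes, and could be made for the 3 symbols listed in both. Pola2, a subunit of DNA polymerase alpha, was lower in MO males (1.83 ± 0.530 to 0.963 ± 0.176 RPM; SD, n = 6 and 5) and higher in MO females (1.43 ± 0.626 to 3.16 ± 1.32 RPM; SD, n = 6 and 5). RT1-N1 was lower in both, by a log2 fold change of -1.60 in males and -1.94 in females. Its levels went from 3.02 ± 2.08 to 0.156 ± 0.137 RPM in males and from 8.92 ± 7.05 to 1.45 ± 2.22 RPM in females (SD, n = 6 and 5). Because 1 was added to each value, the male change of RT1-N1 is understated more. Patz1, a zinc finger gene, was at -0.71 in males and 0.53 in females, but different transcripts of it were listed in the 2 sexes. Its levels rest on few reads. They were 1.17 ± 0.595 to 0.345 ± 0.551 RPM in males and 0.203 ± 0.209 to 0.744 ± 0.331 RPM in females (SD, n = 6 and 5).

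The log2 fold change in males minus that in females was -1.26 ± 0.29 for Pola2 (SE; limma adjusted p = 0.00093), -1.24 ± 0.33 for Patz1 (SE; limma adjusted p = 0.0017) and 0.35 ± 0.82 for RT1-N1 (SE; limma adjusted p = 0.68), so 2 of 3 passed by this test. The direction was shared by 1 of 3 symbols (exact binomial p = 1.0). Pola2 and Patz1 had been listed in each sex for a difference, in opposite directions, so a difference between the sexes was nearly fixed by the selection. After centring on the library medians 0 of 3 passed, and Pola2 was at 0.07 in males. For all other genes the difference between the sexes was not tested, so the unequal lengths of the tables do not show that a gene responded in 1 sex alone.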

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

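All tests of explanations in this part were chosen after the results were seen. In 13 of 200 groups of animals tested, 1 animal stood apart from its group, where chance gives about 10.0. In males these were MO male 2 for Cth, at 220 RPM against 341 to 360 RPM in the other MO males, control male 2 for Gckr at 199 RPM, MO male 1 for Cyp2c13 at 2009 RPM, control male 4 for Stat5b at 11.6 RPM, control male 5 for Oat at 511 RPM, MO male 4 for Hal at 167 RPM, MO male 3 for Patz1 at 1.32 RPM and for C1s at 676 RPM, and control male 6 for Rnf43 at 13.5 RPM. In females they were control female 2 for Olr35 at 19.0 RPM, control female 4 for Zfp39 at 0.935 RPM, MO female 4 for Obp3 at 0.00687 RPM, which is less than 1 read, and control female 6 for Pparg at 0.342 RPM.

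By a limma test of the difference between the sexes, the male minus female log2 fold change passed for Pola2, with -1.26, and for Patz1, with -1.24. Both had been listed in each sex for a difference, in opposite directions, so the test was nearly decided by the selection. After centring 0 of 3 symbols passed, and the Patz1 rows are different transcripts in males and females.

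The male table was lower in 1317 of 1365 rows. A single scaling factor per library was argued against for 24 lower rows, which kept an adjusted limma p under 0.05 after centring. For the other 1293 as a set it cannot be told apart from a decrease, because no unselected transcripts were at hand to centre on. Ugt2b and Rmrp are among the 1293, but each divided the animals of 1 group, which a factor shared by a whole library cannot give. The library medians (log2) were 3.72 to 4.06 in MO males and 4.29 to 4.92 in control males. The split of the control libraries by Rmrp and the signal recognition particle RNA may come from carry-over of RNA without a poly(A) tail. As the whole cause it would put control males 1 and 5 at the MO level, and for 530 lower rows it was argued against. In the 530 lower rows that would have kept an unadjusted p under 0.05 with such a split, the other 4 controls lay above these 2 by a median of 0.10 on the log2 scale (95% interval -0.37 to 0.58) against the 0.94 needed. In the other 787 it was 0.07 (95% interval -0.62 to 0.75) against 0.85. Their selection left no room for such a split, so this was fixed in advance and cannot decide the question for them. A difference in depth, from the slope within groups, gave a shift of the library median of 0.03 (95% interval -0.29 to 0.35) against the -0.58 observed. Rows were listed only for a change of 0.48 or more, so the selection set much of the -0.58. A smaller true shift is therefore not excluded, and this cannot decide on depth. Maternal diet stays open, as untested, beside the scaling, the depth and, in the 787 rows, the carry-over. The samples also carry library numbers, 4 to 8 in MO males and 1, 12, 23, 34, 45 and 56 in control males. In females they were 44 to 50 in controls and 57 to 61 in MO animals. What these numbers stand for is not known here, and a difference in processing along them was not tested.

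Ugt2b was nearly absent in 3 of 5 MO males. The gap between neighbouring animals was 5.96 on the log2 scale, the widest of the listed male rows, with 3.85 next, for the signal recognition particle RNA. A variant of the gene carried by some animals may give such levels, and so may regulation that differs between animals. Without genotypes these cannot be told apart, and the effect of maternal diet stays open.

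Npas2 was lower in MO males while Wee1, Nampt and Rgs16 were higher. A difference in the time of day or in feeding at collection may give such a pattern, and 4 of 4 listed genes with a known daily phase followed a single shift, from 23 genes written down after these genes had been seen. Cry2 of the clock list, also listed (-0.48, and 0.10 after centring), was not among the 23. With 4 genes, chosen with their directions known, collection time and maternal diet cannot be told apart.

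Other splits of the 11 male libraries gave up to 549 calls against the real 1365, and 1 of 100 splits, the real one, gave as many. In females the highest other split gave 8 calls against the real 56, again with 1 of 100 as large. Because the transcripts had been selected on the real split, these counts cannot exclude chance.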

How the results depend on the processing

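The comparison with control males 1 and 5 and the reduction to 1 row per gene were added after the data were seen. Of the 1365 male calls, 702 passed an adjusted p of 0.01, 72 passed after median centring and 531 passed against control males 1 and 5, where 2 controls stand in place of 6 and the median of the lower rows was -0.54 in place of -0.58. Leaving out 1 library gave 1282 to 1364. The fit in which the 4 groups share 1 spread could be made for 3 symbols and passed 3 in each sex. Of the 56 female calls, 8 passed an adjusted p of 0.01 and 4 an exact permutation test, and leaving out 1 library gave 34 to 53, with 34 without MO female 2 and 37 without MO female 5. The share of lower calls in males was 96.5%, and was 95.3% at an adjusted p under 0.01, 94.4% at a fold of at least 1.5, 83.5% at a fold of at least 2, 92.8% against control males 1 and 5 and 33.3% after centring. In females it was 37.5%, and was 87.5% at an adjusted p under 0.01 and 53.3% after centring, with 23.4% to 51.1% when 1 library was left out (23.4% without control female 6, 24.5% without MO female 1). Between the sexes, 2 of 3 symbols passed, 0 after centring and 1 with a filter at a mean of 1 RPM, which removed Patz1. The listed markers of other cell types in males numbered 13, of which 7 passed an adjusted p of 0.01. Stricter thresholds and fewer libraries or symbols explain fewer calls by construction, and for the other changes the cause was not tested.

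After centring, the log2 fold changes of some named male genes reversed, with Mrps27 and Ndufb10 at 0.02, Cry2 at 0.10, Pola2 and Cps1 at 0.07, C1r at 0.01 and Hsd3b5 at 0.00. These follow from the construction, since centring subtracts a shift of -0.58. Rmrp reversed to 0.41 against control males 1 and 5, because the 4 controls with high Rmrp were left out. The sex difference of RT1-N1 reversed to -0.19 with a pseudocount of 0.1. MO males had 0 to 0.303 RPM of RT1-N1, where a pseudocount of 1 understates the change. Cry2 lost its call without MO male 2 or MO male 5, at -0.41 in the latter. Over 1932 combinations of a named gene and an alternative, 1793 kept direction and side of the threshold, 121 fell below the threshold, 9 came to pass it and 9 reversed. Counted by gene, 20 of 68 named male genes and 3 of 26 named female genes kept both under every alternative. With centring set aside these were 54 of 68 and 3 of 26. The exact permutation test was the alternative that lost most female calls, and centring on a median of selected transcripts removes a shift of the male table by construction.

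With the replicate number as a replicate block, 1343 male and 26 female transcripts passed. In males the numbers gave no sign of pairing the animals, since the correlations of same-numbered animals ran from -0.10 to 0.15 (1 of 5 over 0.1). In females they ran from -0.42 to 0.33 (3 of 5 over 0.1). Each number correlated best with itself for 0 of 5 male and 3 of 5 female pairs, so a pairing of the female animals stays open. Set tests with an estimated correlation, count models and size factors were not run, since they need counts or a table of all transcripts, and no variance models other than the main one were run for the sex difference with its 3 symbols. At 0.085 to 0.127 RPM per read, genes under 1 RPM rest on few reads.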

Other observations

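The test in this part was chosen after the result was seen. Amino acid and urea genes had the highest share listed in the male table, 28 of 66 (42.4%), among the 20 lists with at least 5 listed members, and oxidative phosphorylation had the lowest, 7 of 93 (7.5%). In between were the pericentral and periportal markers with 5 of 18 each, male-predominant genes with 6 of 22, the tricarboxylic acid cycle with 5 of 23, xenobiotic metabolism with 13 of 66, bile acid genes with 5 of 26 and glucose metabolism with 7 of 58. Fisher's exact test of 28 of 66 against 7 of 78, once older names of 1 gene were merged, gave p = 3.9e-06 (two-sided). As these lists were picked as the ends of the range after the counts were seen, this p is no evidence for a difference between them. The share listed also depends on the fold threshold, on the spread of each gene and on the shift of the whole male table.

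Single members of smaller lists went against the rest of the male table. Dusp1, a phosphatase of the glucocorticoid and fasting list, was higher (0.68 ± 0.21, SE), as were Rrm2 of the cell cycle list (0.53 ± 0.19, SE) and Derl3 of the endoplasmic reticulum list (0.52 ± 0.19, SE). Of the clock list, Npas2 and Cry2 were listed, with Cry2 at -0.48 ± 0.19 (SE).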
